A study of Mus musculus with 2 samples.

How the data were processed

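Small RNA from wild-type C57BL/6 mouse hippocampus at 6 months of age was measured by miRNA sequencing in 2 libraries, which the labels number as biological replicates 1 and 2 of 1 group. The deposited tables hold raw read counts per annotated miRNA gene, 1 table per library, and the read counts were not normalised before they were deposited. Per the file headers, the reads were placed on mm10 with GENCODE release M21. The aligner and the counting program are not given in the sources used here. The labels cite a different version of the adapter-trimming protocol for each library, and what differs between the versions is not given in the sources used here. Each table lists 2202 genes and 4 summary rows, with 3 columns of counts that were taken, from their sums, as counts without regard to strand, on the strand of the gene and on the opposite strand.

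The counts on the strand of the gene were used throughout. The column choice was checked on the values: 99.954% of the opposite-strand counts in replicate 1 and 99.959% in replicate 2 equalled the sense counts of another annotated miRNA gene that overlaps on the other strand, and 123 and 153 opposite-strand counts remained unmatched. The column without strand gives no count to Mirlet7e and Mir191, which are overlapped in this way, and 1 and 3 counts to Mir126a. In each column every read stood in exactly 1 row, so a read that aligned to more than 1 place was in no gene's count. The summary rows were left out of library sizes and tests. In replicate 1 they held 15.1% of the 11106392 reads as unaligned, 43.8% as aligned to more than 1 place and 2.92% as aligned to 1 place outside the miRNA genes, and in replicate 2 they held 11.4%, 45.7% and 3.005% of 12627039 reads. The counts left on miRNA genes were 4247092 and 5041568. At this depth 3 counts, the limit that a count of 0 allows, correspond to 0.706 CPM in replicate 1 and 0.595 CPM in replicate 2. Intervals of shares and of ratios are exact 95% binomial intervals (Clopper-Pearson) and cover counting error only, since the labels name no molecular identifiers.

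All 2202 genes were matched by identifier to the M21 annotation, from which positions, overlapping genes on the same strand and hairpin sequences were taken. A hairpin was searched against all other annotated hairpins that do not overlap it for shared stretches of 20 bases, and 1087 genes shared at least 1. Hairpins that overlap each other were not compared. Sequence copies outside the annotated hairpins were not searched. Mature arms were not separated, since the counts are per hairpin gene.

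CPM was computed from the sum of counts on miRNA genes. A gene was called detected at 10 CPM or more in both libraries. Differences between the libraries were tested per gene with an exact two-sided binomial test of the replicate 2 count within the sum of both libraries, for 522 genes with a sum of at least 10 counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. The quasi-likelihood test of edgeR needs replicated groups and could not be fitted to 1 library against 1. Log2 ratios are replicate 2 over replicate 1 with 0.5 counts added to each. The biological coefficient of variation was estimated with edgeR (estimateDisp, an intercept-only design, TMM scaling, genes kept by filterByExpr). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 were used.

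The 22 lists of miRNA genes were fixed before the data were examined: neuron-enriched, oligodendrocyte, microglia and blood leukocyte, erythroid, vascular, choroid plexus and ependyma, hindbrain and spinal cord, epithelial, sensory organ, pituitary and hypothalamus, muscle and heart, liver gut and pancreas, pluripotent cell, testis X cluster, let-7, miR-17-92 and paralogues, Dlk1-Dio3, miR-29, miR-30, miR-181, Sfmbt2 cluster families and multi-copy mature sequences. They come from textbook knowledge, some genes stand in more than 1 list, and they hold 306 distinct genes of the tables, of which the detected ones are given per list. The list entry Mir18a matched no gene and was left out. The median log2 ratio of a list was placed among the medians of 10000 random lists of the same size matched on mean level in 20 bins, as a description of these libraries. The genes named were set by a rule fixed before the data were examined: the 20 with the highest mean CPM, the 4 of each list with the highest mean CPM, and, among genes with a mean of at least 100 counts per library, the 5 with the largest log2 ratio in each direction. Genes named beyond this rule are said to have been chosen after their values were seen.

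The procedures were tested on simulated data. For the comparison of replicate 2 with replicate 1 with counting error only, the binomial test called 38.5% of genes changed 1.25-fold, 74.6% of genes changed 2-fold, 86.4% of genes changed 4-fold and 0.606% of 330 unchanged genes, over 524 tested genes that included low counts. Simulated coefficients of variation of 0.1, 0.3 and 0.5 were estimated as 0.0989, 0.305 and 0.478. A simulated list of 20 genes shifted by a log2 ratio of 3 reached percentile 100, and a list of 20 unshifted genes stood at percentile 93.0. That shift is larger than any list median reported here, so the simulation does not show how smaller lists or smaller shifts would fare.

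The alternatives tried were the counts without strand, CPM minimums of 1 and 100, TMM and DESeq2 scaling, other count filters, 5 counts added in place of 0.5, the DESeq2 dispersion, the shares of genes ranked 2 to 11, the lists without multi-copy genes and the removal of each replicate. A linear trend on hairpin GC content was removed as an alternative added after the data were seen. No test between conditions was made, because the samples form 1 group.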

Results

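Small RNA was sequenced from adult mouse hippocampus (C57BL/6, strain B6NCrl, 6 months old). The labels describe the samples as RNA evaluation of wild-type mouse layer of hippocampus, and that description does not name the layer. The samples formed 1 group of 2 libraries, which the labels number as biological replicates 1 and 2. They describe a tissue and the spread between its replicates, and hold no comparison between conditions. The labels describe the tissue as male, although their sex field reads as not collected. Both libraries carry the same donor identifier and the labels do not state that they came from separate animals, so the spread between them may be technical. The replicate 1 library held 11106392 reads, of which 4247092 (38.2%, exact 95% interval 38.2 to 38.3%) were counted on annotated microRNA (miRNA) genes. The replicate 2 library held 12627039 reads, of which 5041568 (39.9%, exact 95% interval 39.90 to 39.95%) were counted on miRNA genes. Levels are given in CPM, counts scaled to the reads counted on miRNA genes, as mean ± SD over n = 2 libraries. Positions refer to mm10. The labels name no molecular identifiers, so PCR copies could not be told from molecules, and all intervals and floors cover counting error only. A miRNA gene stands here for its whole hairpin, since the counts do not separate the mature arms.

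The first question was which miRNAs make up the profile of these hippocampus libraries. Ranks and shares here cover only reads aligned to 1 place, and they do not rank miRNAs whose reads align to several places. Mir139, which lies in introns of the overlapping protein-coding genes Pde2a and Gm45837 (ENSMUSG00000065446.1, chromosome 7, 101475376 to 101475443), had the highest counted level in both libraries, with 154950 ± 2333 CPM (15.5% ± 0.233 of counted reads; SD, n = 2). It was followed by 3 genes of the let-7 family, regulators of developmental timing and differentiation. Mirlet7b, over an exon of the noncoding gene Lncppara (ENSMUSG00000065564.1, chromosome 15, 85707319 to 85707403), had 80245 ± 17701 CPM. Mirlet7i (ENSMUSG00000065406.3, chromosome 10, 122985640 to 122985724) had 72729.9 ± 4702 CPM, and Mirlet7g, in an intron of Wdr82 (ENSMUSG00000065440.1, chromosome 9, 106178840 to 106178927), had 69643 ± 7645 CPM. Mir127, an imprinted gene of the Dlk1-Dio3 region expressed from the maternal allele (ENSMUSG00000070076.2, chromosome 12, 109592846 to 109592915), reached 50774 ± 2462 CPM. Mir744, in an intron of the kinase gene Map2k4 (ENSMUSG00000076460.1, chromosome 11, 65734733 to 65734832), reached 36532 ± 9499 CPM. Mirlet7e (30775 ± 5446 CPM), Mirlet7d (27658 ± 10244 CPM), Mir125a (25895 ± 9063 CPM) and the activity-regulated neuronal gene Mir132 (23338 ± 12352 CPM) completed the 10 genes with the highest counted levels. Together these 10 genes held 57.3% ± 0.197 of the counted reads (SD, n = 2). Their share was 57.1% in replicate 1 (exact 95% interval 57.1 to 57.2%) and 57.4% in replicate 2 (exact 95% interval 57.35 to 57.44%).

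**Figure D1:**
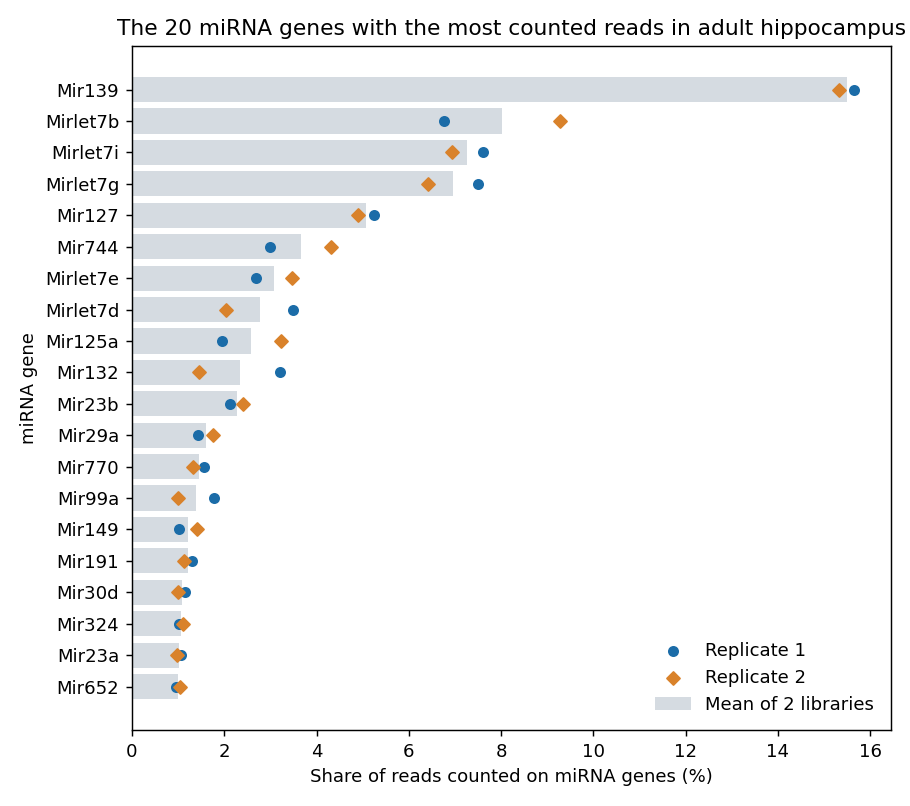
Share of reads counted on miRNA genes (percent, linear axis from 0) for the 20 miRNA genes with the most counted reads, with replicate 1 as circles, replicate 2 as diamonds and the mean of the 2 libraries as bars. Mir139 holds 15.7% and 15.3% of the reads in replicates 1 and 2, and Mir132 and Mirlet7d lie lower in replicate 2 while Mirlet7b, Mir744 and Mir125a lie higher.

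Ranks 11 to 20 were held by Mir23b (22709 ± 1971 CPM), Mir29a (15962 ± 2187 CPM), Mir770 (14429 ± 1721 CPM), Mir99a (13938 ± 5529.6 CPM) and Mir149 (12143 ± 2872 CPM). Next were Mir191 (12129 ± 1297 CPM), Mir30d (10769.7 ± 1043 CPM), Mir324 (10629.9 ± 643 CPM), Mir23a (10195 ± 532 CPM) and Mir652 (10049 ± 617 CPM). Of these, Mir770 overlaps an exon of the imprinted noncoding gene Meg3, Mir149 lies in an intron of the glypican gene Gpc1 and Mir652 in an intron of Tmem164. The 20 genes together held 70.9% ± 0.121 of counted reads (SD, n = 2), and 16 genes stood among the 20 highest of both libraries by counted reads. In replicate 1, 58 genes accounted for 90% of the counted reads, and in replicate 2, 57 genes did. Of 2202 annotated miRNA genes, 302 reached 10 CPM in both libraries, 86 reached 1000 CPM in both, and 1403 had no count in either. The number of genes called detected follows the minimum chosen, with 483 genes at 1 CPM and 187 at 100 CPM in both libraries. A count of 0 allows a level of reads aligned to 1 place of up to 0.706 CPM in replicate 1 and 0.595 CPM in replicate 2, the level of 3 counts. It sets no limit on genes whose reads align to several places.

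Families and genomic clusters were described next. All 12 let-7 genes were detected at 10 CPM or more in both libraries, and they held 28.7% ± 0.0504 of the counted reads (SD, n = 2), the largest share of the 22 lists. Most of that share came from Mirlet7b, Mirlet7i, Mirlet7g, Mirlet7e and Mirlet7d, whereas the 6 genes for let-7a, let-7c and let-7f contributed 1.73% of the let-7 level in replicate 1 and 1.41% in replicate 2. Of the imprinted Dlk1-Dio3 genes on chromosome 12, 44 of 50 were detected and together held 12.6% ± 0.699. They were led by Mir127, Mir770, Mir487b (9392 ± 2956 CPM) and Mir382 (7006 ± 411 CPM). The miR-30 family (6 of 6 detected) held 1.69% ± 0.116, with Mir30d ahead of Mir30a (3996 ± 363 CPM), Mir30e (1628 ± 243 CPM) and Mir30c-2 (293 ± 28.8 CPM). The miR-29 family (4 of 4) held 1.67% ± 0.236, nearly all from Mir29a, with 495 ± 135 CPM for Mir29c, 143 ± 27.3 CPM for Mir29b-2 and 124 ± 6.17 CPM for Mir29b-1. The miR-181 family (6 of 6) held 0.426% ± 0.0349, led by Mir181b-2 (1688 ± 156 CPM), Mir181d (1473 ± 175 CPM), Mir181c (847 ± 21.5 CPM) and Mir181a-1 (203 ± 44.9 CPM). Of the miR-17-92 cluster and its paralogues, associated with cell proliferation, 7 of 15 were detected and held 0.275% ± 0.00130. Mir93 (1395 ± 145 CPM) and Mir92-1 (551 ± 233 CPM) led them, ahead of Mir17 (325 ± 73.1 CPM) and Mir106b (253 ± 5.60 CPM). Of the families named for the large cluster in Sfmbt2, 6 of 81 genes were detected (0.0873% ± 0.0151). The highest counted levels were those of Mir467d (397 ± 116 CPM) and Mir669c (186 ± 62.5 CPM), with Mir669o (88.4 ± 10.2 CPM) and Mir467e (65.1 ± 16.5 CPM) next. These hairpins share sequence with others of the cluster, and their counts cover only the reads that aligned to 1 place.

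Reads that aligned to more than 1 place entered no gene's count, and they made up 43.8% of the reads in replicate 1 (exact 95% interval 43.7 to 43.8%) and 45.7% in replicate 2 (exact 95% interval 45.6 to 45.7%). The levels of genes whose mature sequence stands at several loci therefore rest on the part of their reads that aligned to 1 place. Of these multi-copy genes, 38 of 60 were detected and held 3.32% ± 0.0608 of the counted reads (SD, n = 2). They were led by Mir128-1, Mir219a-2, Mir138-1 and Mir138-2. The multi-copy genes for miR-124, a neuronal miRNA, and miR-9, a miRNA of neural cells, were counted as follows. Mir124a-1 had 6 and 8 counts in replicates 1 and 2, Mir124a-2 had 2 and 0, and Mir124a-3 had 5 and 5. Mir9-1 had 480 and 610 counts, Mir9-2 had 10 and 8, and Mir9-3 had 32 and 257. The miR-124 genes, Mir9-1 and Mir9-2 are named outside the rule for named genes and were chosen after their values were seen.

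Markers of the cell types of the tissue were compared next. Of the neuron-enriched miRNA genes, 20 of 25 were detected, and they held 20.4% ± 1.45 of the counted reads (SD, n = 2). Mir139 alone made up 72.9% of that level in replicate 1 and 78.9% in replicate 2. Without it the list summed to 58147 CPM in replicate 1 and to 40889.9 CPM in replicate 2. Mir132 followed, then Mir128-1, in an intron of R3hdm1 (chromosome 1, 128202361 to 128202430), with 6433 ± 393 CPM. Mir138-1 stood at 3276 ± 85.3 CPM and, from the multi-copy list, Mir138-2 at 2954 ± 146 CPM. Of the oligodendrocyte genes, 2 of 4 were detected (0.730% ± 0.210). They were Mir219a-2 (5037 ± 1989.6 CPM) and Mir338 (2254 ± 111 CPM, in an intron of Aatk), both tied to oligodendrocyte differentiation. Mir219a-1 had 10.5 ± 1.12 CPM, below the minimum in replicate 2, and Mir219b, annotated on the strand opposite Mir219a-2, had 0 counts in both libraries. All 3 vascular genes were detected (0.861% ± 0.0221). The endothelial gene Mir126a, over an exon of Egfl7, stood at 6366 ± 934 CPM, and the smooth muscle genes Mir143 and Mir145a stood at 2001 ± 644 and 245 ± 68.5 CPM. The microglia and leukocyte list (3 of 7 detected, 0.279% ± 0.0214) was led by Mir150 (2044 ± 134 CPM), a lymphocyte miRNA, and Mir146 (662 ± 72.5 CPM). Mir155 (54.2 ± 0.310 CPM) and the myeloid gene Mir223 (8.84 ± 3.81 CPM) came next. Erythroid miRNAs, a sign of blood in the tissue, summed to 22.7 ± 3.80 CPM (1 of 4 detected). Among them, Mir486 stood at 12.7 ± 3.64 CPM and Mir3107 at 1.38 ± 0.290 CPM, and Mir451a had 37 and 35 counts and Mir144 0 and 8 counts in replicates 1 and 2. Mir486 and Mir3107 are annotated over each other on opposite strands. Sequence shared between them was not searched, and any reads that aligned to more than 1 place are missing from both levels and from the sum. The neuron-enriched level was 73.1 and 73.7 times that of the microglia and leukocyte list, and 36.9 and 22.1 times that of the oligodendrocyte list, in replicates 1 and 2. These ratios rest largely on Mir139 and cover only reads aligned to 1 place. Without multi-copy genes, 11 of 25 neuron-enriched, 2 of 4 oligodendrocyte and 7 of 7 microglia and leukocyte genes remain. The lists therefore lack different parts of their reads, and the ratios do not compare their full levels. Members of these lists can be expressed in other cells, so the sums describe lists of miRNAs and not shares of cells.

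**Figure D2:**
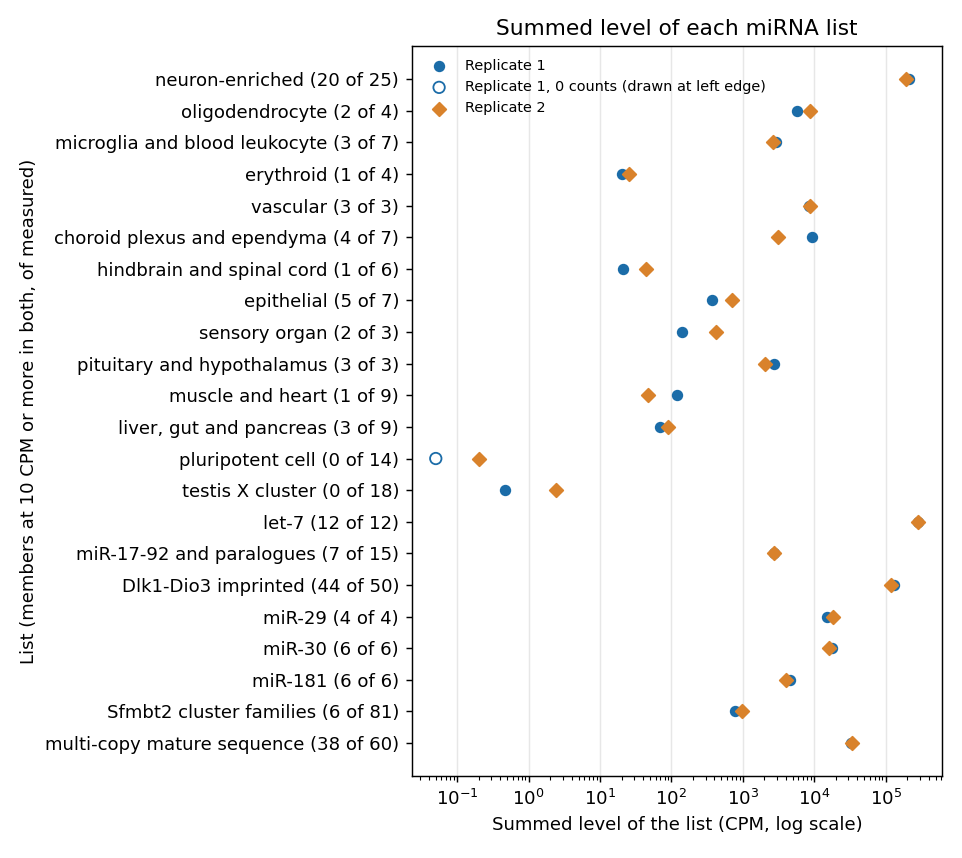
Summed level of each of the 22 miRNA lists (CPM, log axis), with replicate 1 as circles and replicate 2 as diamonds; an open circle at the left edge marks a sum of 0 counts. The let-7 list reaches 28.7% of counted reads, the erythroid list 22.7 CPM, and the choroid plexus and ependyma list lies at 9225 CPM in replicate 1 and 3149 CPM in replicate 2.

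Markers of tissues that a dissection of the hippocampus could also hold were measured in the same way. The choroid plexus and ependyma list (4 of 7 detected) summed to 9225 CPM in replicate 1 and 3149 CPM in replicate 2. Its leading member was Mir204, in an intron of Trpm3, at 4941 ± 3056 CPM, followed by the ciliated-cell genes Mir34c (1127 ± 1176 CPM), Mir34b (90.6 ± 71.0 CPM) and Mir449a (22.8 ± 7.29 CPM, in an intron of Cdc20b). The pituitary and hypothalamus list (3 of 3) summed to 2379 ± 458 CPM, with Mir7b at 1772 ± 383 CPM, Mir375 at 447 ± 96.8 CPM and Mir7-2 at 160.3 ± 21.3 CPM. The epithelial list (5 of 7) summed to 541 ± 235 CPM, led by Mir200b (219 ± 178 CPM), Mir429 (152 ± 11.9 CPM), Mir200c (109.5 ± 58.3 CPM) and Mir203 (26.3 ± 17.3 CPM). The sensory organ list (2 of 3) summed to 283 ± 204 CPM, with Mir183 at 218 ± 154 CPM, Mir182 at 62.5 ± 48.8 CPM and Mir96 at 2.01 ± 0.518 CPM. The hindbrain and spinal cord list (1 of 6), made of miRNA genes of the Hox clusters, summed to 32.7 ± 16.9 CPM. Mir10a stood at 15.3 ± 5.31 CPM and Mir10b at 12.2 ± 5.98 CPM, with Mir615 at 5 and 44 counts and Mir196b at 0 and 1 counts in replicates 1 and 2.

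Lists of more distant tissues were measured as well. The muscle and heart list (1 of 9 detected, 83.6 ± 50.9 CPM) rested on Mir206 (79.4 ± 51.9 CPM), with Mir499 at 4.03 ± 1.04 CPM and Mir1a-1 and Mir133b at 1 count each over both libraries. The liver, gut and pancreas list (3 of 9, 79.9 ± 15.5 CPM) was led by the hepatocyte gene Mir122 (37.1 ± 7.54 CPM), then Mir194-2 (23.3 ± 0.681 CPM), Mir192 (10.9 ± 1.12 CPM) and Mir217 (5.96 ± 4.76 CPM). None of the 14 pluripotent cell genes was detected at 10 CPM, and the list held 1 count over both libraries, on Mir290b, with 0 counts for Mir302a, Mir302b and Mir302c. None of the 18 genes of the testis-expressed X-chromosome cluster was detected at 10 CPM either. They summed to 0.471 CPM in replicate 1 and 2.38 CPM in replicate 2. Mir470 had 1 and 4 counts, Mir741 had 0 and 3, Mir465 had 0 and 2, and Mir878 had 1 and 1.

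The second question was how closely the replicates matched. Across the 302 genes detected in both libraries, log2(CPM + 1) values correlated with Pearson's r = 0.977 and Spearman's rho = 0.973, which is a correlation across genes, and genes are not independent replicates. Of these genes, 211 (69.9%) lay within 1.5-fold of each other and 28 lay over 2-fold apart. The gene with the highest counted level, Mir139, differed by a log2 ratio of −0.03 (replicate 2 over replicate 1). Mir132, in an intron of the noncoding gene 1700016P03Rik (chromosome 11, 75173682 to 75173747), was the only gene of the 20 with the most counted reads that lay over 2-fold apart, at 32072 CPM in replicate 1 and 14605 CPM in replicate 2 (log2 ratio −1.13, exact 95% interval −1.15 to −1.12). The biological coefficient of variation, the spread between replicates beyond counting error, was 0.329 over 422 genes by edgeR, and it was 0.144 from the median gene-wise dispersion of DESeq2.

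Among 276 genes with a mean of at least 100 counts, the genes furthest below in replicate 2 were Mir26a-1, Mir1298, Mir34c, Mir222 and Mir34b, and each passed an exact two-sided binomial test of the 2 libraries' counts. Mir26a-1, in an intron of Ctdspl (chromosome 9, 119031796 to 119031885), had 622 counts in replicate 1 and 19 in replicate 2 (log2 ratio −5.24, exact 95% interval −6.02 to −4.62). It shares its mature sequence with Mir26a-2 and its count covers only reads that aligned to 1 place. Mir1298, in an intron of the serotonin receptor gene Htr2c (chromosome X, 147064905 to 147065002), stood at 2117 CPM in replicate 1 and 259 CPM in replicate 2 (log2 ratio −3.03, −3.11 to −2.94). The neighbours Mir34c (chromosome 9, 51103034 to 51103110) and Mir34b (chromosome 9, 51103562 to 51103645) had log2 ratios of −2.73 (−2.81 to −2.65) and −1.80 (−2.04 to −1.57). Mir222 (chromosome X, 19146893 to 19146971) had a log2 ratio of −2.09 (−2.13 to −2.05), from 4948 CPM to 1164 CPM. The genes furthest above in replicate 2 were Mir3547, Mir9-3, Mir200b, Mir1930 and Mir182, which passed the same exact test. Mir3547, in an intron of Baiap3 (chromosome 17, 25245551 to 25245638), stood at 22.6 CPM in replicate 1 and 172 CPM in replicate 2 (log2 ratio 2.92, 2.62 to 3.25). Mir9-3 (chromosome 7, 79505264 to 79505353), a multi-copy gene, had 32 and 257 counts (log2 ratio 2.74). Mir200b (chromosome 4, 156055681 to 156055750) had a log2 ratio of 1.89, Mir1930 (chromosome 10, 77641224 to 77641307) of 1.81 and Mir182 (chromosome 6, 30165918 to 30165992) of 1.79. Over all 522 genes with at least 10 counts, 266 passed the exact binomial test after Benjamini-Hochberg adjustment at 0.05, 147 of them higher and 119 lower in replicate 2. This test compares 2 libraries' reads and not conditions, and at this depth it calls small differences. Scaling by TMM or by DESeq2 size factors moved every log2 ratio by −0.07 or −0.08 and turned the split of calls to 123 higher and 135 lower, and to 122 higher and 135 lower.

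**Figure D3:**
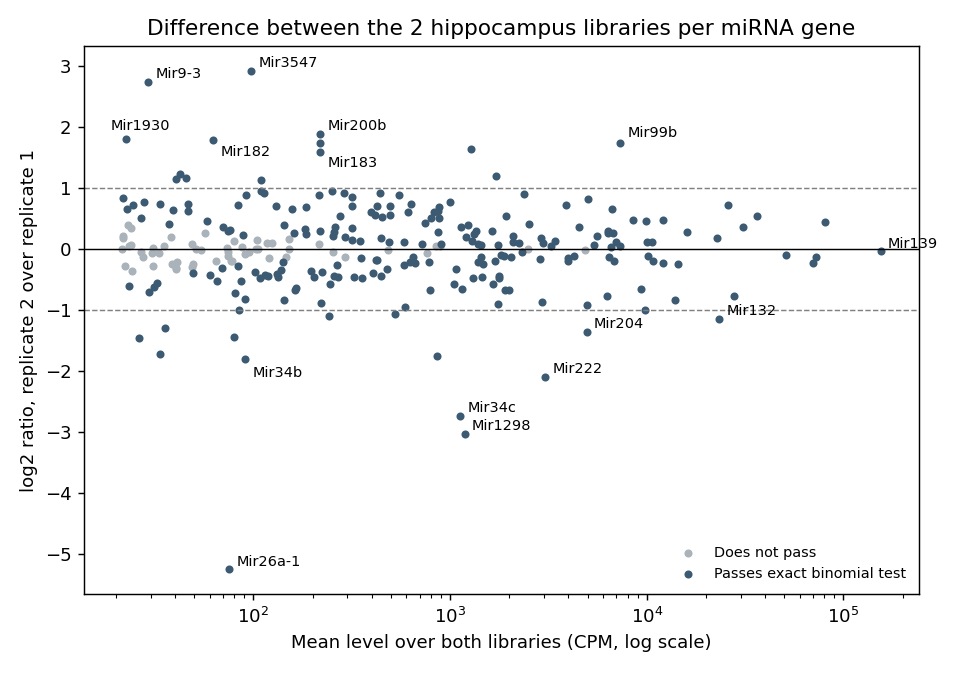
Log2 ratio of CPM, replicate 2 over replicate 1 (vertical axis), against the mean level over both libraries (CPM, log axis) for the 276 miRNA genes with a mean of at least 100 counts per library; dark points passed the exact binomial test, and dashed lines mark 2-fold. Mir26a-1 (−5.24) and Mir1298 (−3.03) lie lowest and Mir3547 (2.92) and Mir9-3 (2.74) highest, while Mir139 lies at −0.03; Mir99b was labelled after its value was seen.

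Lists that could mark a difference between dissections were compared as groups. In the choroid plexus and ependyma list, 3 of 5 members with at least 10 counts (Mir204, Mir34c and Mir34b) passed as lower in replicate 2, Mir449a passed as higher (log2 ratio 0.66), and Mir211, with 25 and 20 counts, did not pass. Mir211 was chosen after its values were seen. The median log2 ratio of the list was −0.56, at percentile 1.09 of 10000 random lists of the same size and level. It was −1.35 over the 5 members with at least 10 counts, at percentile 0.155. In the sensory organ list, Mir183 (log2 ratio 1.59, 1.44 to 1.74) and its neighbour Mir182 passed as higher in replicate 2, and Mir96 did not pass. The list median was 1.59, at percentile 99.1. In the hindbrain and spinal cord list, Mir10a, Mir10b and Mir615 passed as higher in replicate 2. The list median was 1.18, at percentile 99.7, but it lies between Mir10b (1.03) and Mir196b, which had 0 and 1 counts. With 5 counts added in place of 0.5 the median was 0.34, at percentile 98.9, and the list summed to no more than 44.6 CPM in either library. These 3 lists lay outside the central 95% of random lists. Of the 22 lists, 19 could do so, since the random lists matched to the muscle, pluripotent and Sfmbt2 lists had no spread. Chance would put 0.95 of 19 outside on average if list members shifted independently of each other. Mir182, Mir183 and Mir96 are neighbours, as are Mir34b and Mir34c, and the random lists did not keep neighbours together. The expected 0.95 may therefore be too low and the percentiles too extreme. The percentiles describe these 2 libraries and are not p-values.

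The other lists lay inside the central 95%. In the let-7 list 4 genes passed as higher, among them Mirlet7b (0.45) and Mirlet7e (0.36), and 8 as lower, among them Mirlet7d (−0.77). The median was −0.30, at percentile 2.68, and at percentile 2.46, just outside, among random lists of genes with at least 10 counts. In the counts without strand the let-7 median stood at percentile 5.88, and without multi-copy genes it was −0.18, at percentile 16.3. The vascular list had a median of −0.58 (percentile 6.01), with Mir143 (−0.67) and Mir145a (−0.58) lower and Mir126a (0.30) higher in replicate 2. Medians were −0.03 (percentile 28.7) for the neuron-enriched list, −0.06 (55.1) for the oligodendrocyte list and −0.22 (11.7) for the microglia and leukocyte list. They were 0.48 (78.2) for the erythroid list and −0.44 (10.6) for the pituitary and hypothalamus list. For the epithelial list the median was 0.16 (59.7), with Mir200b and Mir200c (1.14) higher and Mir203 (−1.45) lower in replicate 2. For the liver, gut and pancreas list it was 0.20 (85.9). For the families, medians were 0.34 (83.3) for miR-29, −0.15 (22.3) for miR-30 and −0.22 (13.0) for miR-181. They were −0.21 (30.8) for miR-17-92 and its paralogues, −0.000730 (36.3) for Dlk1-Dio3 and −0.23 (3.83) for the multi-copy genes. The oligodendrocyte median was 0.10 (60.7) over its 3 members with at least 10 counts, which leave out Mir219b, and the erythroid median was −0.23 (50.0) in the counts without strand. The Dlk1-Dio3 median lay near 0 and changed sign under 2 alternatives. At the main setting, sums and medians differed in sign for 4 of the lists given so far in this paragraph. The summed level was higher in replicate 2 for the oligodendrocyte list (5817 and 8786 CPM in replicates 1 and 2, with Mir219a-2 at a log2 ratio of 0.83), the vascular list (8456 and 8769 CPM), the miR-17-92 list (2737 and 2755 CPM) and the multi-copy list (32785 and 33646 CPM), while their medians over all members were negative. Most members of the muscle, pluripotent, testis and Sfmbt2 lists had no count in either library, so their medians carry no information on a difference. In the muscle list Mir206 passed as lower in replicate 2, with a log2 ratio of −1.44 (−1.68 to −1.21).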

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

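All tests in this part except the one of library scaling were chosen only after the results they bear on had been seen.

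Signal was found in parts of the tables that the levels above do not use, above the limit that a count of 0 allows. Reads aligned to more than 1 place made up 43.8% of the reads in replicate 1 and 45.7% in replicate 2. Reads aligned to 1 place outside the miRNA genes made up 2.92% and 3.005%. The strand opposite the miRNA genes held 267592 counts in replicate 1 and 370961 in replicate 2. Of these, 267469 and 370808 were the sense counts of overlapping miRNA genes on the other strand and so are already in the levels above. Only 123 and 153 opposite-strand counts were not used there.

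The let-7 genes whose mature sequence stands at several loci had lower levels than the other let-7 genes: the 6 genes for let-7a, let-7c and let-7f lay −5.83 log2 CPM from the 6 others on average. This value is the size of the difference as it was first seen, so it decides nothing about the cause. Reads aligned to more than 1 place entered no gene's count, so the counts of these 6 genes hold none of the reads that fit several loci. They do not measure the level of the shared mature sequences, and this may account for the difference. Whether the true level of these miRNAs in hippocampus is also low cannot be told. The reads aligned to more than 1 place equalled 114% of the reads counted on genes, and the tables do not say which miRNAs they hold. No other biological explanation was tested.

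Gene levels differed between the replicates by more than counting error, with 266 of 522 genes passing the exact binomial test and a chi-square statistic of 481 per degree of freedom. The counts argue against library scaling as the cause, since 257 genes passed under the scaling that left the fewest, against 266. Hairpin GC content was related to the log2 ratios across 276 genes (Pearson's r = 0.214, permutation p = 0.0003; Spearman's rho = 0.286, permutation p = 2e-05; both adjusted over 2 relations to at most 0.0003; genes are not independent replicates), but 29 genes lay over 2-fold apart before the trend was removed and 29 after it. The adapter-trimming protocol that the labels cite differs along with the replicate, and it was not tested. No biological explanation was tested, as the design holds 1 group.

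Mir34c, Mir34b and Mir204, which mark ciliated cells and choroid plexus, were lower in replicate 2, with a mean log2 ratio of −1.96. The values argue against hairpin GC content as the whole cause, since the mean was −1.84 after the GC trend was removed. Less choroid plexus or ependyma in replicate 2 may account for the difference. The other list members with at least 10 counts had a median log2 ratio of 0.0483. Mir449a passed as higher (0.66), and Mir211 (25 and 20 counts, chosen after its values were seen) did not pass. Mir34c, Mir34b and Mir204 were set apart because they had passed as lower. The 2 members left over are therefore those that had not, and their median cannot decide on this explanation. They also go both ways at low counts. The explanation cannot be told apart from a change within other cells, in which list members can be expressed. No other biological explanation was tested.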

How the results depend on the processing

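Removal of the hairpin GC trend was chosen only after the results were seen, and the other alternatives before the data were examined. The number of genes detected in both libraries, 302 at 10 CPM, was 483 at 1 CPM and 187 at 100 CPM, as the minimum itself sets, 285 without strand, 303 with TMM library sizes and 313 to 319 with a single library. The share of the 10 genes with the most counted reads, 57.3%, became 60.6% in the counts without strand, which drop Mirlet7e, and 44.0% for ranks 2 to 11, which leave out Mir139; it was 57.3 to 58.3% with a single library, each with its own 10 genes. The genes that differed between the libraries numbered 240 to 267 under 5 alternatives, against 266; of these, 243 were shared with TMM scaling. The coefficient of variation, 0.329, lay at 0.329 to 0.348 under 3 alternatives and at 0.144 with the median gene-wise DESeq2 dispersion, and the cause was not tested. Detected list members numbered 93 to 168 under 6 alternatives, each within 1.5-fold of the number at the main setting. The lists outside the central 95% of random lists, 3, stayed at 3 or 4 under 6 alternatives and became 5 after removal of the GC trend, which added the pluripotent and Sfmbt2 lists and turned the Sfmbt2 median from −0.247 to 0.0540; 13 of 14 and 67 of 81 of their members had no count, so the trend alone moves them. Further values covered single genes, detected members per list, the number of genes over 2-fold apart and the medians of 6 lists. These 6 lists lay outside the central 95% in at least 1 setting. Of the further values, 187 kept their direction and their side of the threshold, or for numbers of genes lay within 1.5-fold. Among these, 3 list medians changed in size by more than 1.5-fold: hindbrain (1.18, and 0.34 with 5 counts added), choroid plexus (−0.56, and −1.35 with at least 10 counts per member) and let-7 (−0.30, and −0.18 without multi-copy genes). Another 24, all of them numbers of detected members per list, moved, 2 list medians (let-7 and pluripotent) moved outside the central 95% and 1 (Sfmbt2) changed sign. Of the 16 other lists, the median changed sign under at least 1 alternative for 4 (oligodendrocyte, erythroid, testis and Dlk1-Dio3) and only in size, by more than 1.5-fold, for 8. With at least 10 counts per member, the muscle, pluripotent and testis lists gave no value, and without multi-copy genes the oligodendrocyte, pituitary, miR-29, miR-181 and multi-copy lists gave none. The biological coefficient of variation and the comparisons of libraries need both libraries and were not repeated without either. No paired analysis was possible because the samples form 1 group. Depth limits genes near the floor of 3 counts, and 1403 of 2202 genes had no count.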

Other observations

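The tests of neighbouring genes were chosen only after the log2 ratios had been seen, and the test of introns before its result was seen.

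Several genomic neighbours differed between the replicates in ways the lists do not cover; the genes in this paragraph beyond Mir1298, Mir222, Mir132, Mirlet7e and Mir125a were chosen after their values were seen. In the serotonin receptor gene Htr2c on chromosome X, intronic Mir1298 and Mir1264 were lower in replicate 2 (−3.03 and −1.72 log2 ratio), Mir448 was less so (−0.32), and Mir764 did not pass the exact binomial test (147 and 181 counts). Mir221 and Mir222, which lie side by side on chromosome X, were both lower in replicate 2 (−1.002 and −2.09), as were Mir132 and Mir212 on chromosome 11 (−1.13 and −0.67), a pair induced by neuronal activity. The Spaca6 neighbours Mir99b, Mirlet7e and Mir125a were all higher in replicate 2, with log2 ratios of 1.75, 0.36 and 0.73. Mir195a and Mir497 were also both higher (1.64 and 0.28).

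Neighbouring miRNA genes may shift together because they share a primary transcript. Among genes with a mean of at least 100 counts, the log2 ratios of 79 genes in 33 clusters outside the Dlk1-Dio3 region (gaps of at most 10 kb, 1 strand) had a within-cluster correlation of 0.388 (one-sided permutation p = 0.0045, adjusted p = 0.013 over 6 tests). The value was 0.417 after the GC trend was removed, and 0.266 (permutation p = 0.019) without Mir34b and Mir34c, the lowest value with any 1 cluster left out. The correlation measures the shared shift and not its cause. Neighbours already seen to differ together, such as Mir221 and Mir222, stayed in the test, so its p-value gives no independent support. In the Dlk1-Dio3 region a shared shift was not shown, as 45 genes in 3 clusters had a within-cluster correlation of −0.0151 (permutation p = 0.57). Genes that all stay near the average ratio add little to this value. It therefore does not exclude that members of a cluster moved together. Over all 36 clusters the correlation was 0.0301 (permutation p = 0.14). Members of 1 cluster can also lie in both directions, as Mir467d (0.60) and Mir467e (−0.52) did.

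The hypothesis that miRNA genes inside introns of protein-coding genes hold more reads than those elsewhere was tested on the 302 detected genes. The 114 intronic genes had a median of 199.9 CPM and the 188 other genes a median of 316 CPM, a difference of −0.66 on the log2 scale (two-sided permutation p = 0.176), so intronic genes were not shown to hold more reads. They held 42.3% of the counted reads in replicate 1 and 44.0% in replicate 2, of which Mir139 made up a large part.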
